A study of Homo sapiens with 20 samples.

How the data were processed

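Gene expression had been measured on 20 Affymetrix HG-U133 Plus 2.0 arrays, which carry several short-oligonucleotide probe sets for many human genes. Per the labels' protocols, the RNA came from commercially supplied primary human mammary epithelial cells. The cells had been infected for 17.5 h, at a multiplicity of infection of 150, with an adenovirus carrying either the B form of the human progesterone receptor or β-galactosidase. They were then treated for 16 h with 10 nM R5020 (promegestone, a synthetic progestin) or with the ethanol vehicle, 10 arrays each. The labels do not say which virus was used for which array, and the arrays were grouped by treatment alone. They name 2 RNA extraction kits without assigning them to arrays. Nothing in the labels says that the 10 samples of a group were separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

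The deposited values were on a log2 scale, as their range shows, and per the submitters' processing notes they were made by the authors with the robust multi-array average (RMA), with the version not given in the sources used here. Biotin-labelled RNA had been made by a single-cycle in vitro transcription protocol, per the labels. RMA as a method subtracts background, brings the probe distributions of the arrays to a common shape and summarises the probes of a probe set by median polish. Values on this scale are relative, so a change in the total RNA of the cells cannot be seen. Fold changes of genes near the background, and of genes near the top of the scale, are compressed. The deposited table held 54613 probe sets. Its values ran from 2.80 to 15.20 with a median of 5.43 and quartiles of 4.21 and 7.87, and the array medians lay between 5.40 and 5.50. No further scaling was applied for the main results. Arrays give no count depth, and the number of arrays limits the precision.

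Probe sets were named from the platform's annotation table, in which 41091 had 1 gene symbol, 1801 had several and 11721 had none. Symbols were checked through Entrez identifiers against a RefSeq gene table of the GRCh38.p14 assembly, which matched 41037 of them and changed 0. That table was otherwise used only to find which genes neighbour each other, and no coordinates are given because the deposited values name no genome build. Probe sets with several symbols or none were not named, and 59 probe sets of genes on the Y chromosome, XIST or TSIX were left out. Other X-linked genes were kept. Each of the remaining 19740 genes was represented by the probe set with the highest mean over all 20 arrays. Other probe sets of the named genes were fitted separately at the probe-set level.

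R5020 and vehicle arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates). A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05. The moderated test had 24.6 degrees of freedom, of which 6.59 came from the prior. Expression is given as the group mean ± SD of 10 arrays, and changes as log2 differences, R5020 minus vehicle, with the standard error (SE). Intervals are 95% intervals. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, which asks whether a list moved relative to the other genes, with Benjamini-Hochberg adjustment over 29 lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list moved, on balance, in 1 direction. The lists held 492 genes, of which 443 were measured, and the rest were not analysed here.

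The groups, the tests, the 29 lists, the named genes and the alternatives were fixed before the data were examined, except where another origin is stated. The genes to be named were the 12 with the largest rise and the 12 with the largest fall among the called genes, without Y-linked genes and XIST. They further included PGR, NR3C1, TNFAIP3, TNIP2, NFKBIA, CXCL8, IL6, IL1B, CCL2, CXCL1, PTGS2, FKBP5 and TSC22D3 whatever their values, and up to 4 members of each list with the smallest adjusted p. Any other gene was named after its values had been seen.

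The fit and the list test were tested on simulated data with the same 19740 genes and arrays, in which 200 genes had been changed, 50 at each of 4 sizes, and 20 further genes of a shifted list by -0.5. Of genes changed by 0.3 on the log2 scale 64% were recovered, of those changed by 0.6 98%, and of those changed by 1 or 2 100%, together 181 genes, and 15 of the 20 list genes were called. Among all 214 calls 18 were false, or 8.41%, and 0 of 20 unshifted lists were called. The simulated genes were drawn independently of each other. Members of real lists were correlated, with an estimate of 0.59 for interferon-stimulated genes, for example. The 0 of 20 therefore does not show how often real lists would be called falsely. The simulation changed far fewer genes than the 32.8% called in the real data, so its adjusted threshold was stricter. Its arrays were also drawn independently of each other. The recovered shares and the 8.41% therefore describe the simulation and not the sensitivity or the false calls of the real comparison.

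The alternatives were the replicate number as a block, centring each array on its median, a further quantile normalization, the brighter 50% of the genes, the mean of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, eBayes with trend and robust options, array weights, the first residual principal component as a covariate, and leaving out each array in turn. Probe sets with these endings can match several transcripts. Leaving out R5020 arrays 1 and 2 together was added after the data had been seen, because endocrine peptide transcripts were high on both. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.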

Results

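The data described how the transcripts of primary human mammary epithelial cells differed after 16 h with 10 nM R5020, a synthetic progestin, from those of vehicle-treated cells. All cells had been infected beforehand with an adenovirus that carried the B form of the human progesterone receptor or β-galactosidase. There were 10 arrays of R5020-treated and 10 of vehicle-treated cells, and 19740 genes were compared. The title of the series names the inhibition of inflammatory responses by the progesterone receptor as its subject, so the question put to the data was which inflammatory and hormone-responsive transcripts differed with R5020. The lowest correlation between any 2 arrays of 1 group was 0.991, the highest between the groups 0.986, and the first principal component, which separated the treatments, held 59.9% of the variance.

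PGR, the progesterone receptor gene, was at 14.54 ± 0.19 (SD, n = 10) in vehicle and 14.64 ± 0.17 in R5020 arrays on its brighter probe set. These levels lay between 14.30 and 14.90 on all 20 arrays, near the highest value of 15.20 in the data, where differences are compressed. No array stood apart with a low PGR level, which argues against a mix of receptor and β-galactosidase arrays. The other PGR probe set was near background, at 4.56 ± 0.18 in vehicle and 4.68 ± 0.26 in R5020 arrays. The PGR difference was 0.09 (SE 0.08, limma adjusted p = 0.398). NR3C1, which encodes the glucocorticoid receptor, was at 11.23 ± 0.16 in vehicle and 11.10 ± 0.11 in R5020 arrays (limma adjusted p = 0.137), and that difference of -0.13 passed the threshold only without vehicle array 2 (-0.17, limma adjusted p = 0.0198). ESR1, the estrogen receptor α gene, stood at 6.37 ± 0.14 in vehicle and 6.27 ± 0.13 in R5020 arrays (limma adjusted p = 0.280) on its brightest probe set, which ends in _x_at. On the other ESR1 probe sets, none of which passed the limma test, group means ran from 3.98 to 6.22, mostly near background.

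With R5020, the steroid-induced gene FKBP5 was among the called rises, and CXCL8, IL1B, PLAU and TNFSF10 were among the 12 largest falls. FKBP5, a co-chaperone of steroid receptors and a well-known target of them, rose from 9.18 ± 0.22 to 12.44 ± 0.15, a 9.61-fold increase. CXCL8, the neutrophil chemokine interleukin-8, fell from 8.93 ± 0.35 to 4.19 ± 0.35, near background, or at least 26.7-fold, and IL1B fell 8.73-fold. PLAU, the urokinase plasminogen activator, fell 17.8-fold, and TNFSF10, the death ligand TRAIL, also fell 17.8-fold. In each of these 5 genes, all 10 R5020 arrays lay on 1 side of all 10 vehicle arrays.

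With limma and Benjamini-Hochberg adjustment, 3442 genes were higher and 3023 lower with R5020, together 32.8% of those tested. At a minimum change of 1.5-fold there were 1738 genes (918 higher, 820 lower), at 2-fold 671 (362 higher, 309 lower), and at 4-fold 78 were higher and 60 lower. Most called changes were small, with a median absolute log2 change of 0.36. The groups did not overlap at all for 2125 genes, or 10.8%, where chance would give 0.214 genes. The median change of all tested genes was -0.01.

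SCRG1, a small secreted protein gene first described in scrapie-infected brain, had the largest rise, from 5.07 ± 0.42 to 10.99 ± 0.36 (60.4-fold, limma adjusted p = 3.3e-20). CAPN6, a calpain without protease activity, rose 30.4-fold, and TCHH, the hair follicle protein trichohyalin, 27.0-fold. SCNN1G, the γ subunit of the epithelial sodium channel, rose 23.6-fold on its brighter probe set, while its other probe set, with a mean of 4.85, differed by -0.01. Near background, the other SCRG1 probe set rose by 0.29 and the dimmest of CAPN6 differed by 0.09. TFPI2, an inhibitor of serine proteases, rose 20.6-fold, the meiotic recombination gene MND1 18.3-fold, PRR15 18.1-fold and the caveolar coat protein gene CAVIN2 16.9-fold. The AP-1 transcription factor gene FOS rose 15.8-fold, the inositol trisphosphate kinase gene ITPKA 15.5-fold, the aquaglyceroporin gene AQP9 15.4-fold and NELL2 14.6-fold. The vehicle means of MND1 (4.04), SCNN1G (4.23), TCHH (4.44) and CAPN6 (4.61) lay near background, where changes are compressed, so these folds are lower bounds and the order of the genes is that of the measured changes. The adjusted p of these 12 genes was at most 2.82e-15 by limma.

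HSPA6, an inducible heat shock protein of the 70 kDa family, had the largest fall, from 11.61 ± 0.37 to 6.01 ± 0.24 (48.5-fold, limma adjusted p = 1.14e-21). Its other probe set fell by 4.12 on the log2 scale, and HSPA6 is closely similar in sequence to other genes of its family. The aggrecan-cleaving proteases ADAMTS5 and ADAMTS1 fell 16.3-fold and 11.3-fold, and AMIGO2, a cell adhesion protein gene, 16.0-fold. The cell cycle repressor E2F7 fell 10.2-fold, G0S2, an inhibitor of lipolysis, 9.44-fold, and CYP1B1, a cytochrome P450 that oxidises estradiol, 9.15-fold. KMO, an enzyme of tryptophan breakdown, fell 8.67-fold. For CXCL8, PLAU, TNFSF10, ADAMTS5, ADAMTS1, E2F7, CYP1B1, IL1B and KMO, every further probe set of the gene fell as well. Of all 79 named genes with more than 1 probe set, 45 had every probe set past the threshold in 1 direction. None of the 79 had a probe set past it in the opposite direction.

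**Figure D1:**
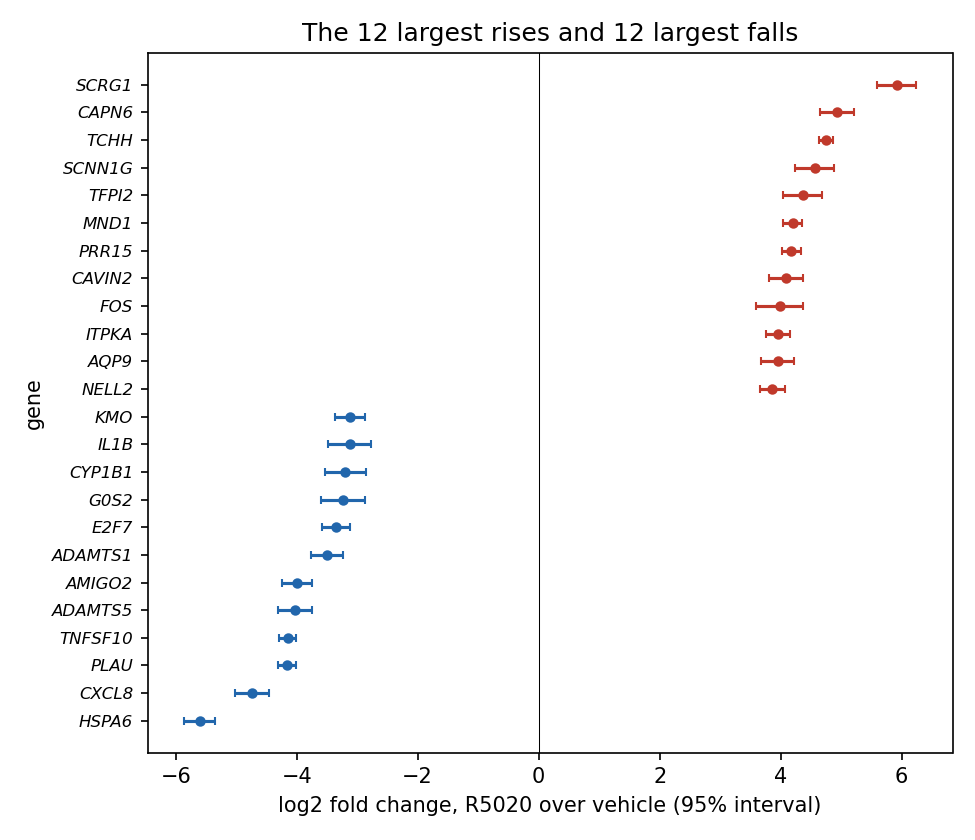
The 12 genes with the largest rise (red) and the 12 with the largest fall (blue), each as a point at its log2 fold change of R5020 over vehicle with its 95% interval. Rises ran from 3.87 for NELL2 to 5.92 for SCRG1 and falls from -3.12 for KMO to -5.60 for HSPA6, and no interval came near 0.

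Of the 29 gene lists, 10 shifted relative to the other genes in camera with the preset correlation, and 5 of these were also called with an estimated correlation. In each list the 4 members with the smallest adjusted p had been set to be named, and any further member was named after its values had been seen. Where no count adjusted over the list alone is given, it was identical to the count over all genes. For CXCL11, CXCL6, CCL20, HPGD, KDR, KIF20A, ZBTB16 and BTC, 1 or both group means lay near background, from 4.05 for KIF20A to 4.94 for BTC, so the changes given below for them are compressed and are lower bounds, as is that of CCL2.

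Among 28 measured progestin-responsive genes, 13 rose and 7 fell (14 and 7 adjusted over the list alone). ZBTB16, a transcriptional repressor, rose from 4.73 ± 0.14 to 7.86 ± 0.26, a log2 change of 3.12, and PPL, the desmosomal plaque protein periplakin, rose by 2.97. ERRFI1, a feedback inhibitor of the EGF receptor, rose by 1.24. TSC22D3, the glucocorticoid-induced leucine zipper gene, rose by 1.03 on its brightest probe set and by 0.97 on another, and the third, near background, differed by 0.06. Further rises were those of the MAP kinase phosphatase gene DUSP1 (2.39), MAOA (1.51), the kinase gene SGK1 (1.29) and MUC1 (1.14). ID4, CCND1, CDKN1A, WNT4, MYC, BCL2L1 and CEBPD fell, with CCND1, the cyclin D1 gene, at -0.82 and ID4 at -0.88. The list had a median change of 0.13, a mean of 0.60 and a camera adjusted p of 0.00131, which was not kept (adjusted p = 0.115 with an estimated correlation). Among the brighter 50% of the genes its median was 0.68.

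Cytokine and inflammatory NF-kB targets mostly fell: of 32 measured, 23 fell and 2 rose (25 and 2 adjusted over the list alone), with a median change of -0.80. CXCL2, a neutrophil chemokine, fell by 2.44 on its brightest probe set, CXCL1 by 1.75, and LIF, a cytokine of the interleukin-6 family, by 1.44. CXCL1 remained well expressed, at 11.28 ± 0.28 in vehicle and 9.53 ± 0.26 in R5020 arrays. IL6 fell by 0.52 (SE 0.12), from 7.32 ± 0.33 to 6.80 ± 0.25, and CCL2, the monocyte chemokine, fell by 0.51 (SE 0.15) close to background, from 4.21 ± 0.50 to 3.69 ± 0.16. Other members that fell were CXCL6 (-2.86), CXCL5 (-2.58), CXCL10 (-2.20), IL1A (-1.91), CCL20 (-1.72) and TNF (-1.33). CXCL11, a chemokine of the same receptor as CXCL10, rose by at least 3.10 from 4.49 ± 0.40, near background, to 7.59 ± 0.27, and the interleukin-36γ gene IL36G rose by 0.82. PTGS2, the inducible cyclooxygenase, was at 8.68 ± 0.38 in vehicle and 8.83 ± 0.44 in R5020 arrays and did not pass the test (limma adjusted p = 0.550). Nor did SOD2 (-0.11, limma adjusted p = 0.771) or, over all genes, CXCL3 (-0.31, limma adjusted p = 0.0802). The shift of the list had a camera adjusted p of 4.11e-12 with the preset correlation (adjusted p = 0.0279 with an estimated correlation). Without probe sets ending in _x_at or _s_at, 9 of the 32 members, CXCL8 among them, were no longer measured, CXCL2 was read from a dim probe set, and the median of the other 23 was -0.38.

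**Figure D2:**
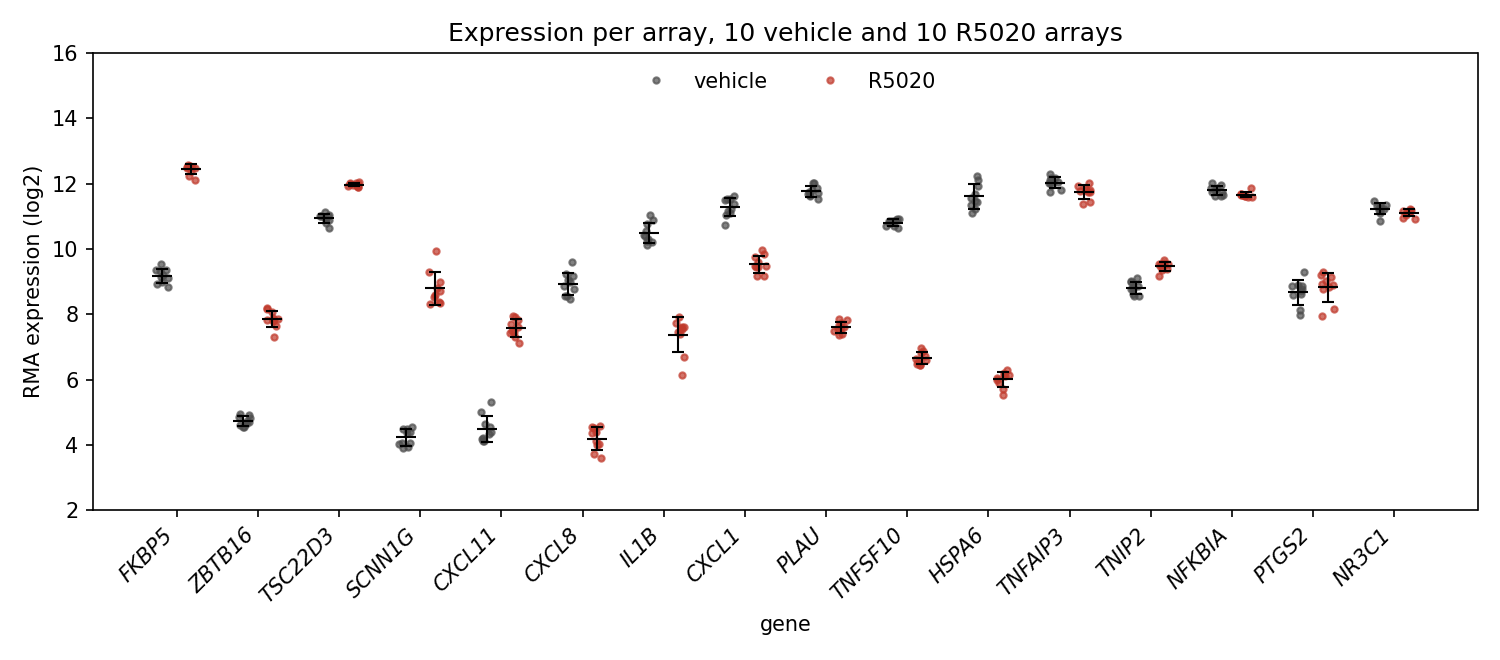
RMA expression (log2) of 16 genes on each of 10 vehicle (grey) and 10 R5020 (red) arrays, with horizontal bars and whiskers for the mean and SD of each group. FKBP5, ZBTB16, TSC22D3, SCNN1G, CXCL11 and TNIP2 were higher on every R5020 array than on any vehicle array, CXCL8, IL1B, CXCL1, PLAU, TNFSF10 and HSPA6 were lower on every one, and the groups overlapped for TNFAIP3, NFKBIA, PTGS2 and NR3C1.

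The regulators of NF-kB themselves moved both ways, 6 of 21 measured rising and 7 falling (6 and 8 adjusted over the list alone), and the list was not shifted (median -0.05, camera adjusted p = 0.728). TNIP2, a partner of the ubiquitin-editing protein A20 that inhibits NF-kB, rose by 0.66 (SE 0.07, 1.58-fold), and all 3 of its probe sets rose. TNFAIP3, which encodes A20, fell by 0.28 (SE 0.08, limma adjusted p = 0.00625), while its other probe set differed by -0.19 (limma adjusted p = 0.0634). NFKBIA, the inhibitor IκBα, differed by -0.13 (SE 0.05, limma adjusted p = 0.0758), a value close to the threshold that passed it in several other settings, for example with array weights (-0.15, limma adjusted p = 0.0200). The atypical inhibitor NFKBIZ fell by 1.17 and the deubiquitinase CYLD by 0.91, whereas NFKBIE, another IκB, rose by 0.56.

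Interferon-stimulated genes were lower or not past the test, with 13 of 24 measured falling and 0 rising (14 and 0 adjusted over the list alone) and a median change of -0.61. At an unadjusted limma p under 0.05, 15 fell and 0 rose. The antiviral proteins IFIT2, IFIT1 and IFIT3 fell by 2.82, 2.71 and 1.65, and RIGI, a sensor of viral RNA, by 1.07. These genes varied widely within a group, as with IFIT1 at 8.61 ± 0.73 in vehicle and 5.89 ± 0.75 in R5020 arrays. The camera call (adjusted p = 1.06e-05) was not kept for this list (adjusted p = 0.472 with an estimated correlation).

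In the prostaglandin pathway, 5 of 12 measured genes rose and 2 fell (5 and 3 adjusted over the list alone). HPGD, which inactivates prostaglandins, rose by at least 2.61, the prostaglandin E2 receptors PTGER2 and PTGER4 by 2.27 and 1.62, the constitutive cyclooxygenase PTGS1 by 1.49, and the prostaglandin D synthase PTGDS by 1.05. The synthases PTGES and PTGES3 fell by 0.45 and 0.34. The median change was 0.09, the mean 0.67 and the camera adjusted p 0.0359, which was not kept (adjusted p = 0.0813 with an estimated correlation). The camera call was also lost without vehicle array 8 (adjusted p = 0.0523), without R5020 arrays 1 and 2 (0.0592) and with the replicate number as a block (0.0629). It was lost as well with the first residual principal component as a covariate (0.0620) and with the mean of the probe sets of a gene (0.0636). The same held without _x_at and _s_at probe sets (0.289) and among the brighter 50% of the genes (0.993).

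All 7 measured heat shock proteins fell, with a median change of -0.89. The co-chaperone DNAJB1 fell by 1.48, HSPH1 by 1.34, the mitochondrial chaperonin HSPE1 by 1.05 and the HSP70 co-chaperone BAG3 by 0.89. This list was called with the preset (camera adjusted p = 2.07e-07) and the estimated correlation (adjusted p = 0.0142). Of 11 measured NRF2 targets, 9 fell and 1 rose, with a median of -0.28 and camera adjusted p of 0.00131 and, with an estimated correlation, 0.0142. Heme oxygenase HMOX1 fell by 2.47, thioredoxin reductase TXNRD1 by 0.83 and SRXN1 by 0.68, while AKR1C1, an aldo-keto reductase that inactivates progesterone, rose by 1.20. Among 14 unfolded protein and amino acid stress genes, 6 rose and 3 fell, and the list was not shifted (camera adjusted p = 0.360). Its stress transcription factor ATF3 fell by 1.20 and DDIT3 and PPP1R15A by 0.55 and 0.41, while XBP1 rose by 0.58, CHAC1 by 0.58 and the asparagine synthetase gene ASNS by 0.55.

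Hypoxia and glycolysis genes fell in 9 and rose in 2 of 14 measured cases, with a median change of -0.42. The glucose transporter SLC2A1 fell by 1.90, the vasodilator peptide gene ADM by 1.16, hexokinase HK2 by 0.98 and the collagen hydroxylase P4HA1 by 0.72, while PFKFB3 and LDHA, both of glycolysis, rose by 0.81 and 0.32. The other HK2 probe sets, with lower means of 6.63 and 5.84, differed by only -0.05 and 0.01. The camera call (adjusted p = 0.000335) was not kept (adjusted p = 0.115 with an estimated correlation). Of 7 metallothioneins, MT1M rose by 1.00 and the other members differed by 0.07 or less, and the list was not shifted (camera adjusted p = 0.539).

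Genes of the extracellular matrix, its proteases and integrins fell in 16 and rose in 2 of 22 measured cases, with a median change of -0.47. Beside PLAU, the stromelysin MMP10 fell by 2.40, the collagenase MMP1 by 2.26 and the collagen receptor subunit ITGA2 by 2.22. PLAUR, the receptor of urokinase, rose by 1.09, and the integrin subunit ITGB1 by 0.16. The camera call (adjusted p = 1.06e-05) was not kept (adjusted p = 0.0975 with an estimated correlation). Of 17 measured TGF-beta and BMP response genes, 11 fell and 3 rose (14 and 3 adjusted over the list alone), with a median of -0.59. The activin antagonist FST fell by 2.08, the activin subunit INHBA fell by 2.01, TGFB2 by 1.65, and ID1 and ID3, inhibitors of differentiation, by 2.42 and 1.62. CCN2, the connective tissue growth factor, and CCN1 rose by 2.32 and 1.91 and ID2 by 1.18. This list was called with the preset (camera adjusted p = 0.000419) and the estimated correlation (adjusted p = 0.0142).

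EGF-family ligands and ERK feedback genes moved both ways, with 8 of 23 measured rising and 7 falling (8 and 8 adjusted over the list alone) and no shift (camera adjusted p = 0.736). Alongside FOS and ERRFI1, SPRY4, BTC, DUSP5 and TGFA rose by 0.81, 0.80, 0.63 and 0.53. The immediate early gene IER3 fell by 2.26, the EGF receptor ligands EREG and HBEGF by 1.61 and 1.47, and PHLDA1 by 1.38. Of 20 genes of the G1/S transition and DNA replication, 6 rose and 3 fell (camera adjusted p = 0.728). The helicase subunits MCM6 and MCM7 went opposite ways, by 0.67 and -0.63, and thymidylate synthase TYMS and the DNA clamp PCNA fell by 0.60 and 0.54. Of 21 mitotic genes, 7 rose and 0 fell, among them AURKA (0.56), NUSAP1 (0.57), CCNB1 (0.43) and KIF20A (0.32), and the list was not shifted (8 and 0 in limma at an unadjusted p under 0.05, median 0.12, camera adjusted p = 0.162).

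Of 15 measured p53 targets, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with a median of -0.20 and camera adjusted p of 0.0178 and, with an estimated correlation, 0.0484. The stress cytokine GDF15 fell by 1.56, the DNA repair gene DDB2 by 1.05, the cyclin-dependent kinase inhibitor CDKN1A by 0.69 and PLK3 by 0.59. The death receptor gene FAS and TP53I3 rose by 0.62 and 0.48. Of 13 apoptosis regulators, 4 rose and 3 fell (camera adjusted p = 0.789), with a median of -0.04 but a mean of 0.05. BIRC2, an inhibitor of apoptosis, rose by 0.92, and the BH3-only gene PMAIP1 by 0.79, with CASP9 and CFLAR at 0.36 and 0.34. The BH3-only genes BCL2L11 and BID fell by 0.59 and 0.51 and the survival gene BCL2L1 by 0.33.

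Clock genes were split, with 3 of 12 measured rising and 6 falling (camera adjusted p = 0.318). CRY1 and PER2, repressors of the core clock, rose by 1.43 and 1.29 and CRY2 by 0.26, whereas BHLHE40 and BHLHE41, repressors of another family, fell by 1.98 and 1.16. Of 11 epithelial ion and water transport genes, 5 rose and 4 fell (camera adjusted p = 0.175). SCNN1A, the α subunit of the sodium channel, rose by 1.74, the water channel AQP3 by 1.18 and SLC12A2 by 0.40, beside SCNN1G and SGK1. The other AQP3 probe sets, with means of 6.76 and 6.56, rose by only 0.24 and 0.30. CLCA2, ATP1B1, CFTR and FXYD3 fell by 0.89, 0.63, 0.79 and 0.27. Of 17 cholesterol and fatty acid synthesis genes, 8 rose and 4 fell (camera adjusted p = 0.162). DHCR7, the last enzyme of cholesterol synthesis, rose by 1.18 and SC5D by 0.33, while INSIG1, SREBF1, SCD and HMGCS1 fell by 0.91, 0.40, 0.39 and 0.29. Among 8 steroid receptor and coregulator genes, NR3C2, the mineralocorticoid receptor gene, fell by 0.83 and NCOA2 by 0.50, while NCOA1 rose by 0.49 (camera adjusted p = 0.357).

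Of 12 basal and myoepithelial markers, 2 rose and 5 fell (3 and 6 adjusted over the list alone). OXTR, the oxytocin receptor gene, rose by 3.77, keratin KRT5 by 0.31, while LAMB3, KRT14, EGFR, MYLK and CDH3 fell by 0.77, 0.23, 0.43, 0.38 and 0.21. Group means of KRT5 and KRT14 lay between 14.2 and 14.6, near the top of the scale, where differences are compressed. This list's median of -0.19 and its camera direction (down, adjusted p = 0.715) differed in sign from its mean of 0.15. Of 18 luminal markers, 3 rose and 6 fell (camera adjusted p = 0.789), with a median of 0.01 against a mean of -0.04. The epithelial transcription factor ELF3 fell by 1.39, KRT19 by 0.62 and ALDH1A3 by 0.45, and MUC1, SLPI and KRT8 rose by 1.14, 0.50 and 0.46. Of 24 cornification genes, PPL rose and KRT16, S100A7, S100A9, S100A8 and TGM1 fell by 1.02, 0.98, 0.72, 0.58 and 0.50 (median -0.09, camera direction down, adjusted p = 0.290). In fry the direction of the basal and the cornification lists was up (adjusted p = 0.617 and 0.485).

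Markers of other cell types were mostly not past the test. Of 11 fibroblast markers, POSTN and THY1 fell by 0.81 and 0.46 (camera adjusted p = 0.288), of 9 leukocyte markers CSF1R fell by 0.54 (camera adjusted p = 0.529), and of 9 endothelial markers KDR rose by 0.63 (camera adjusted p = 0.728). The endocrine peptide transcripts SST and GCG, from no list and named after their values had been seen, were high on R5020 arrays 1 and 2 alone, with SST at 8.69 and 8.59 against at most 4.84 on the other R5020 arrays. Without these 2 arrays, a setting chosen after the data were seen, 3356 genes were higher and 2775 lower. Of 13 ribosomal protein genes, 0 passed the limma test after adjustment and 0 at an unadjusted p under 0.05 (median 0.01, camera adjusted p = 0.789). Of 10 reference genes, PGK1 and HPRT1 fell by 0.22 and 0.17 (1 gene adjusted over the list alone), and HPRT1 lost its call in most other settings, for example with each array centred on its median (limma adjusted p = 0.0846). The reference list was not shifted (median -0.03, camera adjusted p = 0.781).

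**Figure D3:**
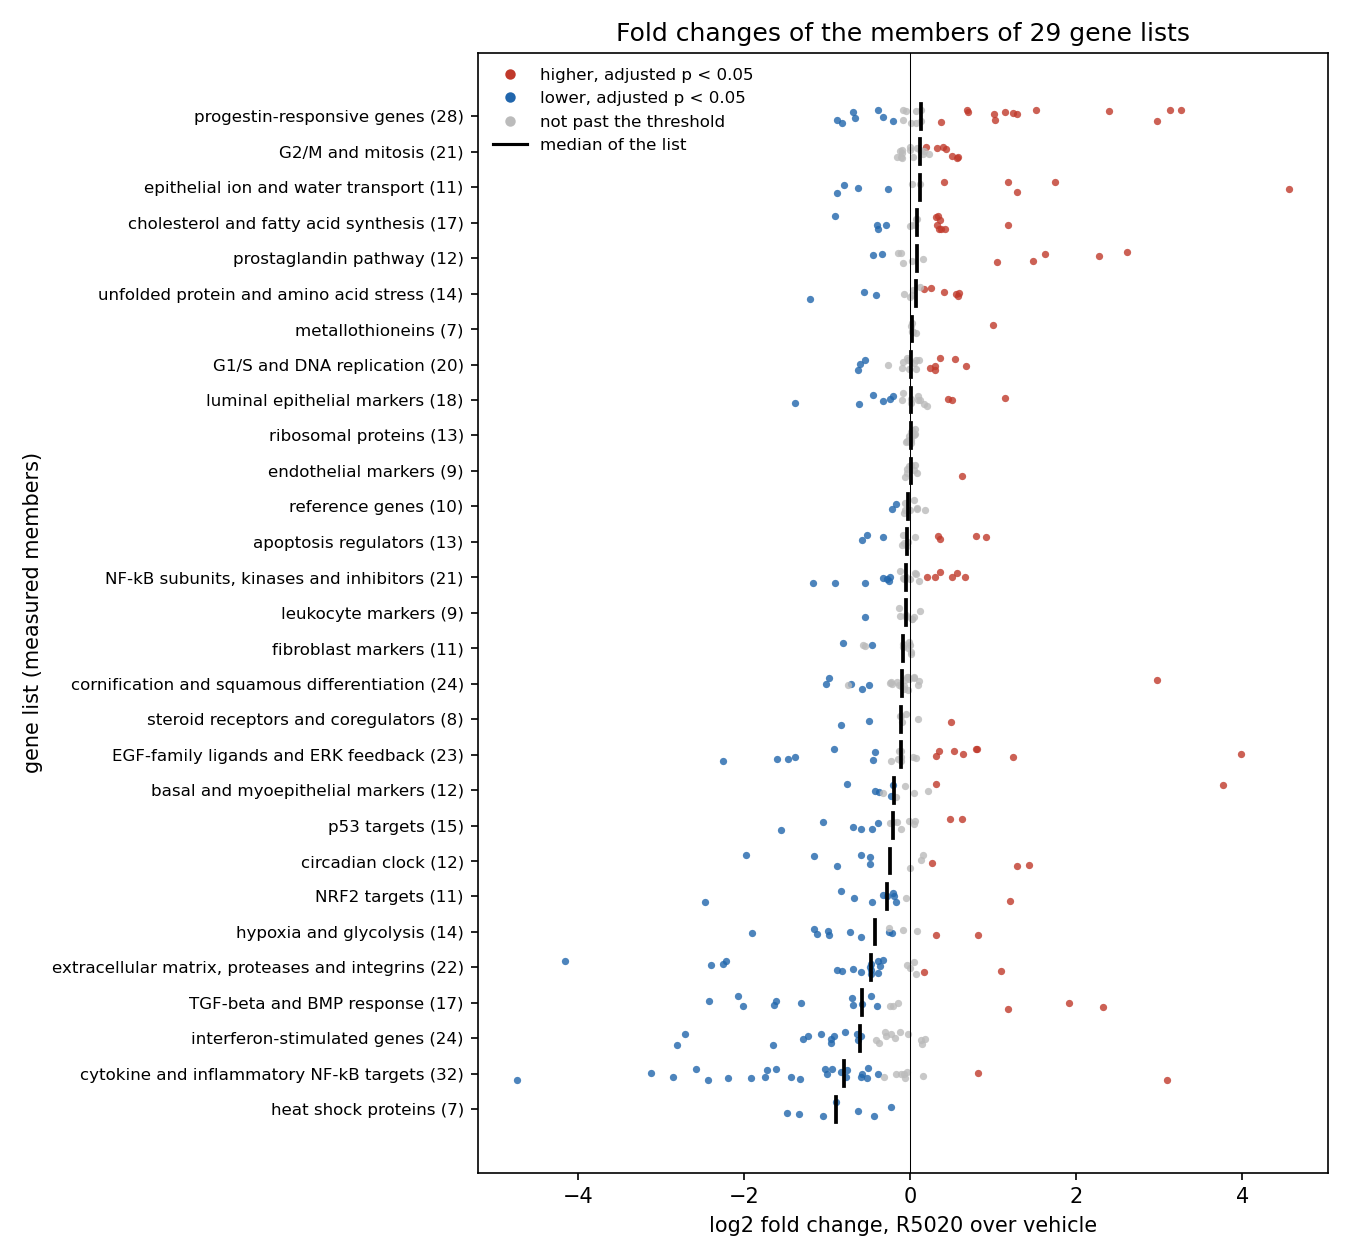
Log2 fold change of R5020 over vehicle for every measured member of the 29 gene lists (number of members in brackets), 1 point per gene, red where higher and blue where lower at the adjusted threshold of 0.05, grey otherwise, with a vertical bar at the median. List medians ran from -0.89 for heat shock proteins to 0.13 for progestin-responsive genes, and most lists held genes on both sides of 0.

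Probe sets ending in _x_at or _s_at can match more than 1 transcript, and 22 of the 125 named genes rest wholly on them, among them CXCL8, PLAU, ADAMTS1, CYP1B1, KMO, G0S2 and TNFAIP3. When they were left out, TSC22D3, CXCL2, AURKA, CCNB1, SC5D, GDF15, ASNS, BHLHE41 and P4HA1 no longer passed the limma test on the brightest probe set that remained. Of these probe sets, that of SC5D had a mean of 6.47 over all arrays and the others lay near background, from 3.38 for P4HA1 to 4.95 for GDF15, so that most of the lost calls say little about the genes. A second probe set of CXCL2 fell by 0.36 (limma adjusted p = 1.02e-05). Also without _x_at and _s_at probe sets, the p53 list was no longer called (camera adjusted p = 0.0855).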

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

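The tests of INS in the arrays with endocrine transcripts and of a swapped vehicle array were chosen only after the result was seen. In 250 combinations of a named gene and a treatment group, the array farthest out was compared with its nearest neighbour, relative to the range of the group. In 10 of them the gap passed the 95% critical value, where chance would give 12.5.

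Among vehicle arrays, SCRG1 was at 4.06 on array 10, below the other arrays at 4.90 to 5.48, and HPGD at 5.10 on the same array, above the others at 4.19 to 4.62. CCL2 was at 5.41 on vehicle array 6 against 3.64 to 4.49 on the others, and IFIT2 at 10.05 on vehicle array 5 against 8.00 to 8.97. Among R5020 arrays, NFKBIA was at 11.87 on array 4 against 11.58 to 11.70, CDKN1A at 12.81 against 12.18 to 12.44, and BAG3 at 11.91 against 11.42 to 11.64, all on that array. NFKBIZ was at 9.39 on R5020 array 5 against 8.84 to 9.05, and BIRC2 at 12.74 on it against 12.42 to 12.58. LAMB3 was at 12.19 on R5020 array 3 against 12.59 to 12.98. Without R5020 array 4, the NFKBIA difference was -0.15 (limma adjusted p = 0.0297).

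Of the probe sets with no gene symbol or several, which the comparison of genes left out, 1630 differed between the treatments (limma, Benjamini-Hochberg), 730 of them higher and 900 lower with R5020. That is 12.1% of these probe sets, and 334 of them changed at least 1.5-fold.

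Vehicle array 8 had 72 genes more than 2-fold below the mean of its group and 1 more than 2-fold above it, against at most 22 such low genes on any other array. A swapped label is argued against, since the array lay at 0.026 on an axis from the vehicle mean at 0 to the R5020 mean at 1. A fault of single probe sets and a lower RNA level of these genes in that sample cannot be told apart: for 42 of the genes another probe set was expressed, and these deviated by a median of -0.35, with quartiles of -1.30 and 0.05. A fault would leave these near 0 and lower RNA would bring them below -0.5, and 19 of the 42 lay below that.

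On R5020 arrays 1 and 2, SST (somatostatin) was at 8.69 and 8.59 against 4.16 to 4.84 on the other R5020 arrays, GCG (glucagon) at 7.04 and 8.18 against 3.69 to 4.29, and TTR at 7.59 and 8.02 against 6.13 to 6.56, while SCG2 was at 5.17 and 4.98 against at most 4.32 and CHGA at 5.51 and 5.67 against at most 4.89. RNA of whole pancreatic islets is argued against by INS, the most abundant islet transcript. INS was at 5.31 and 5.65 against 4.93 to 7.12 on the other R5020 arrays, with a median of 5.36. On vehicle arrays it was at most 5.05. Its difference from the mean of the other R5020 arrays, a mean raised by the array at 7.12, was -0.24, against 4.20 for SST and 3.72 for GCG. RNA of some other endocrine cells, carried over into these samples, may be the source and stays open. The 10 measured endocrine markers that had not been looked at before had a median excess of 0.015, within the range of -0.04 to 0.03 of the 44 other pairs of R5020 arrays. That was the result named in advance as counting against endocrine RNA, but only 2 of the 10 were above the median of all values, markers near background exclude nothing, and the share of such RNA that they could have shown was not tested.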

How the results depend on the processing

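Of the settings compared here, leaving out R5020 arrays 1 and 2 together was chosen only after the result was seen. The counts of higher, lower and 1.5-fold changed genes stayed within 1.5 times their values under all alternatives, and the cytokine shift kept its direction and call under all of them, with medians from -0.78 to -0.87 when 1 array was left out. Leaving out 1 array gave 3306 to 3589 higher and 2877 to 3063 lower genes, 1704 to 1746 changed 1.5-fold, and a progestin-responsive median of 0.12 to 0.15. Without probe sets ending in _x_at or _s_at the cytokine median was -0.38, and 4748 of the 5522 earlier calls still tested were made again, 4745 in the same direction. The progestin-responsive shift of 0.13 lost its call with an estimated correlation (adjusted p = 0.115, against at most 0.0309 in the other alternatives); the cause was not tested. P4HA1 reversed, at 0.0046, without _x_at and _s_at probe sets, where a probe set near background stood for it. Of 3707 values of named genes under alternatives, 3674 kept direction and call, 24 lost the call, most often HPRT1, and 8 gained it, most often NFKBIA. With the replicate number as a block, 3715 genes were higher, 3380 lower and 1739 changed 1.5-fold. The replicate block gave list medians of -0.80 for cytokines and 0.13 for progestin-responsive genes. It ended the prostaglandin call (camera adjusted p = 0.0629) and called cornification (0.0394), both at the preset correlation. In the unblocked fit, cornification had a camera adjusted p of 0.746 with an estimated correlation. With the block 16 interferon-stimulated genes fell and 1 rose, OAS3 by 0.18 (limma adjusted p = 0.0494), named after its value was seen. The interferon list's camera adjusted p with the block and an estimated correlation was 0.209. The numbers were not taken as pairs: 8 of 10 same-number pairs correlated above 0.1 in their deviations (-0.03 to 0.40), short of all 10. Only 2 R5020 and 3 vehicle arrays correlated best with their own number. R5020 arrays 1 to 4 did so with the adjacent number (1 with vehicle 2 at 0.338, 3 with vehicle 4 at 0.392), and arrays 7 to 10 with numbers farther off. The low count therefore does not argue against a factor shared by adjacent numbers. The mean correlation was 0.251 for same-number pairs and -0.03 for other pairs (one-sided permutation p = 8e-05). That permutation took the 10 numbers as independent, while some adjacent numbers resembled each other, so its p may be too small. The deviations were thus related by number or by adjacent numbers, but the source of this stays open, and the unblocked results leave it out. IL1B, for example, was at 6.70 and 6.13 on R5020 arrays 3 and 4 and at 7.40 to 7.92 on the others. The 10 arrays of a group may therefore hold fewer than 10 independent samples, and the limma p-values may be too small as well. The ion transport list was called without _x_at and _s_at probe sets at the preset correlation (camera adjusted p = 0.00932). With all probe sets and an estimated correlation its camera adjusted p was 0.422. In fry, 20 lists were called. Genes with 1 or both groups near the background of about 4, such as CCL2, CXCL8, MND1, SCNN1G, TCHH, CAPN6, CXCL11, CXCL6 and HPGD, have compressed changes.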

Other observations

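The tests of same-numbered arrays, of the other CXCL11 probe set and of single transcripts under separate names were chosen only after the result was seen. Genes beyond the 12 largest changes of each direction were read for what they encode, and those below were chosen after their values were seen. Among the next rises, the oxytocin receptor OXTR rose by 3.77, the sphingosine-1-phosphate receptor S1PR3 by 3.18, and CXCR2, the receptor of CXCL8, by 2.62 from 5.02 ± 0.17 to 7.65 ± 0.69. The transcription factor gene FOXQ1 rose by 3.79, the lipoxygenase ALOX15B by 3.14, the drug efflux pump ABCG2 by 2.74 and TIPARP by 2.64, the last to 13.42 ± 0.22. Among the next falls were CTHRC1 (-3.06), SOSTDC1, an antagonist of BMP and Wnt signals (-2.95), the epithelial transcription factor EHF (-2.77), xanthine dehydrogenase XDH (-2.66), the growth factor gene FGF1 (-2.62), the atypical cadherin FAT2 (-2.62) and the hyaluronan synthase HAS3 (-2.50). Also lower were CD274 and PDCD1LG2, the ligands of the immune checkpoint receptor PD-1, by -2.17 and -1.41, and CASP1, which processes interleukin-1β, by -1.99.

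Genes that neighbour each other in the genome tended to change in the same direction. Of 218 adjacent pairs in which both genes had changed at least 1.5-fold, 158 (72.5%) went the same way. In 10000 shuffles of the directions among the changed genes, with the gene order kept, the median share was 50%. Probes shared between paralogs with like symbols are argued against as the source. Without pairs whose symbols share their first 3 letters, 72.0% of 189 pairs did so (permutation p = 0.0001, the smallest that the shuffles can give). A single transcript measured under separate names is argued against within similar limits. Without antisense, divergent, uncharacterised (LOC) and long noncoding (LINC) symbols as well, the share was 71.2% of 177 pairs. Other noncoding loci, such as LNCAROD beside DKK1, and related genes with unlike symbols, such as CD274 and PDCD1LG2, stayed in. Neither cause was therefore tested in full. A candidate explanation is shared regulation of neighbouring genes, a hypothesis found and tested on the same data. Examples outside gene families were DDAH1 (2.26) and CCN1 (1.91), BLMH (2.68) and CPD (1.26), and E2F7 (-3.35) and NAV3 (-1.60).

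CXCL11 rose while CXCL10 fell, and the other CXCL11 probe set also rose, by 1.94 (95% interval 1.71 to 2.17), so a single faulty probe set does not account for the rise. The mean deviation of the interferon-stimulated genes from the group mean correlated between same-numbered R5020 and vehicle arrays (10 pairs, Pearson r = 0.736, one-sided permutation p = 0.0138, Spearman rho = 0.539, permutation p = 0.0555). Without numbers 6 and 8, whose R5020 arrays lay farthest from the R5020 median, r was 0.704 (permutation p = 0.0476). Number 5, whose vehicle array had the highest deviation of all (0.597), was kept. The value therefore does not show that r was independent of the most extreme arrays. With Benjamini-Hochberg adjustment over the 29 lists the interferon correlation had an adjusted permutation p of 0.0468, and 8 lists passed, among them fibroblast markers and cornification genes (adjusted permutation p = 0.00580 each). All of these permutations took the numbers as independent, although some adjacent numbers resembled each other, so their p-values may be too small.

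The 20 arrays were split into groups of 10 in 100 ways, the real one included. No other split reached the gene counts or the cytokine shift of the real one. A share of 1 in 100 is the smallest that this test can give. The splits treat the 20 arrays as independent. A chance difference between cultures or batches that the arrays of a treatment shared is therefore not excluded. Only 1 split, the real one, called as many genes (6465, highest other 1879), only 1 as many at 1.5-fold (1738, highest other 514), and only 1 had a cytokine median as far from 0 (0.803, highest other 0.539). For the progestin-responsive median 4 of the 100 splits were as large (0.132), and the highest other, 0.140, exceeded the real value. For this median not even a random grouping of the arrays is clearly excluded. The splits that called the most genes besides the real one kept 8 of the 10 arrays of a treatment together.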
